A study of Mus musculus and Rattus norvegicus with 12 samples.

How the data were processed

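Expression was measured on 12 one-colour Affymetrix arrays, 6 hybridised with mouse RNA and 6 with rat RNA. Each species contributed 2 pools of morulae, 2 pools of blastocysts and 2 pools of inner cell masses (ICMs), as the sample titles give them. Per the labels' protocols, total RNA was purified with a micro-scale column kit and biotin-labelled cRNA was made from 6 µg of total RNA. The design text says that more than 100 embryos were pooled. Embryos therefore vary within a pool, and the spread between 2 pools leaves out most of the variation between single embryos. Nothing in the labels says how far the 2 pools of a stage were handled apart, so the p-values measure the spread between these pools, part of which may be technical.

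The deposited values are log2 probe-set values that the authors made with RMA, which is named without a version or settings in the submitters' processing notes. RMA in general subtracts background, equalises the probe intensities of the arrays and summarises the probes of a set on a log2 scale. That the base is 2 was taken from the method, since the table itself does not state it. The table for the mouse holds 16860 rows and that for the rat 11462 rows, each with 1 row per Ensembl gene ID, so no choice between several probe sets of a gene arose. The array type, the probe-set definition and the annotation release are not given in the sources used here. Array medians ran from 6.35 to 6.40 in the mouse and from 5.69 to 5.78 in the rat, and all values were positive, so the genes had not been centred. No scanner intensities or detection calls were used here. The lowest value on any array was 1.53, and values near such a floor carry little information on level. A fold change towards or from that range is therefore a value on the RMA scale and can understate the change in RNA. The 2 tables were processed separately, and no level was compared across them.

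The tables do not pair the Ensembl IDs with gene names. The reference table supplied with the data had no Ensembl entry in any row, and 0 of the 16860 mouse IDs and 0 of the 11462 rat IDs matched it. Genes are therefore given by ID, without name, location or function. The 20 gene lists fixed before the data were examined, the lineage markers and every comparison of matched mouse and rat genes could not be used for the same reason. Markers of trophectoderm or of maternal tissue could likewise not be read. IDs were named by a rule fixed before the data were examined. It takes, per species and comparison, the 5 largest rises and the 5 largest falls among genes past the threshold whose pools did not overlap, and the first 2 of each are printed. Where no gene passed the threshold, the 2 largest differences in each direction with pools that did not overlap are given, a choice made after the values were seen.

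Each species was fitted on its own with limma (version 3.58.1 in R 4.3.3) on the deposited log2 values. One linear model over the 3 stages shared a single estimate of the spread per gene (3 residual degrees of freedom), and eBayes moderated it with 3.05 prior degrees of freedom in the mouse and 2.61 in the rat. Differences were tested two-sided, adjusted by Benjamini-Hochberg over all genes of the table and called at an adjusted p of 0.05. Adjusted p-values in the text are from this fit unless another is named. No exact test of single values was made between stages, because 2 pools against 2 cannot give a two-sided permutation p below 0.333. The fit was tested on simulated data, in which 200 genes per comparison were changed by known amounts around the measured means. A single spread per gene, estimated over the 3 stages, was used. For the mouse blastocyst against the morula, 0% of changes of 1 on the log2 scale, 42% of changes of 2 and 74% of changes of 4 were recovered among 16860 genes. For the rat blastocyst against the morula, the shares among 11462 genes were 2%, 44% and 92%. For the ICM against the blastocyst, changes of 2 were recovered in 30% of cases in the mouse and 40% in the rat. Calls therefore favour large changes. The share recovered also depends on how many genes change, so these shares need not hold for the measured data. The smallest called change between blastocyst and morula was 1.11 in the mouse and 1.60 in the rat.

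A second measure did not depend on a threshold. The difference between 2 stages was taken once in each of 2 pairs of pools that shared no array, and the 2 sets of differences were compared over all genes, with the pools paired by number and crosswise. Their covariance estimates the variance over genes of the differences that recur in both pairs, and its square root is given as the SD of repeated differences. Genes are not independent replicates, so no p-value is attached to it. The share of the morula-to-blastocyst change found in an ICM pool was the covariance of its difference from one morula pool with the difference of a blastocyst pool from the other morula pool, averaged over the combinations and divided by the repeated variance of the blastocyst against the morula. No array entered both sides of any of these covariances. On simulated data, shares set to 50% and 100% came out as 50.7% and 101.1% over the 16860 mouse genes and as 50.4% and 100.8% over the 11462 rat genes.

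The alternatives were quantile normalisation of the deposited values, a shift of each array to a common median, removal of the dimmest 30% of genes, a mean-dependent prior (trend), an added minimum of 2-fold, fits restricted to the 4 arrays of the 2 stages compared, the replicate number as a block, and leaving out each array. Array quality weights, and the alternatives for the second measure, were chosen after the data were seen. The samples were assigned to stages from their titles, and none was left out. No column of other samples was present.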

Results

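Preimplantation embryos of the mouse and the rat were profiled at the morula stage, at the blastocyst stage and as isolated inner cell masses. The morula is the compacted ball of cells that precedes the blastocyst. The blastocyst holds an outer epithelium, the trophectoderm, which forms the placenta, and the ICM, from which the embryo proper and pluripotent stem cells derive. ICMs were freed by immunosurgery, in which antiserum and then serum complement lyse the outer cells. Mouse embryos (B6D2F1) came from superovulated females aged 3 to 5 weeks, and rat embryos (Wistar) from females in oestrus aged 6 to 12 weeks. Rat morulae were taken at embryonic day 4 and rat blastocysts at day 4.5. Antiserum was applied for 30 min in the mouse and for 3 h in the rat. Each of the 3 stages was represented by 2 pools per species, giving 6 arrays per species, and this number limits the precision of every value below. The study set out to follow expression across the formation of the pluripotent ICM in the 2 species. Values are RMA log2 values, means are given ± SD over n = 2 pools, and genes are identified by Ensembl ID because the tables give no names.

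In both species the morula pools lay apart from the blastocyst and ICM pools. The first principal component separated them and held 51.6% of the variance in the mouse and 45.2% in the rat. Mouse blastocyst pools were the most alike of any pair, with a Pearson correlation over genes of 0.991 and 1.21% of genes at least 2-fold apart. They were counted as separate samples because the labels give 2 pools per stage, and the values alone do not exclude repeat arrays of one RNA. Mouse ICM pool 2 correlated at 0.982 with each blastocyst pool, whereas mouse ICM pool 1 correlated at 0.931 and 0.932 with the blastocyst pools and at 0.937 with ICM pool 2. The mouse ICM pools were at least 2-fold apart at 20.1% of genes. In the rat the ICM pools correlated at 0.975 and the blastocyst pools at 0.971. Morula pools correlated at 0.941 in the mouse and 0.939 in the rat, and rat morula pool 1 correlated as highly with rat blastocyst pool 1 (0.940) as with the second morula pool.

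**Figure D1:**
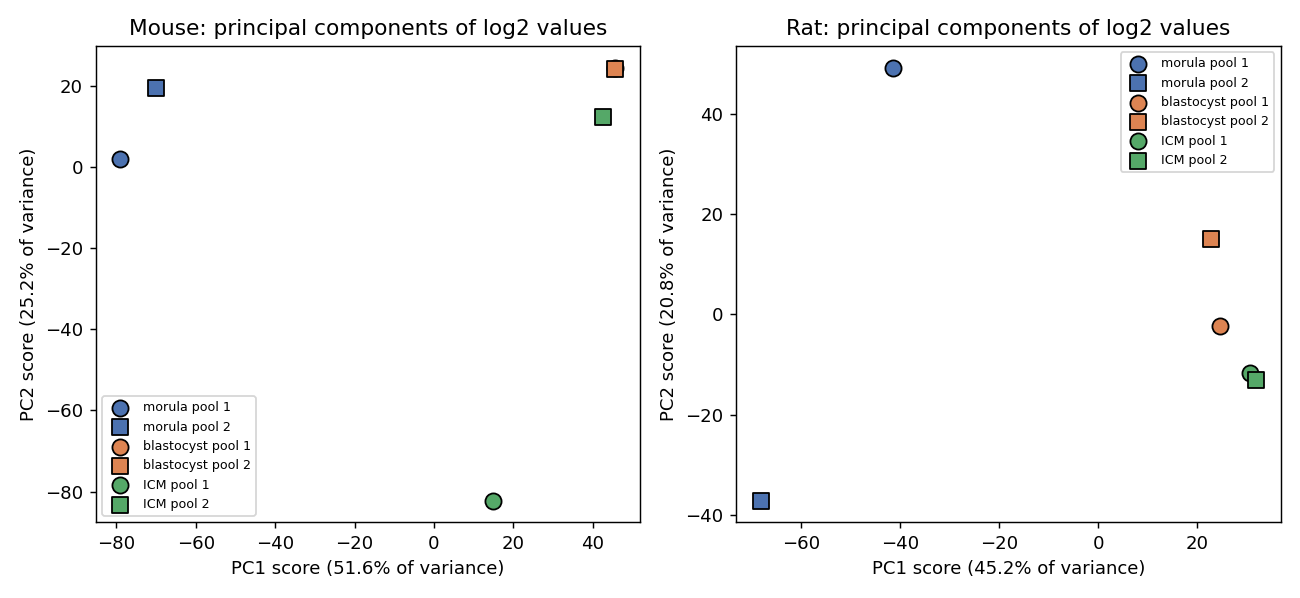
Scores of each array on the first and second principal components of the log2 values, in the mouse (left) and the rat (right), with colour for the stage and marker shape for the pool. Morula pools have negative PC1 scores in both species, and mouse ICM pool 1 lies at -82.2 on PC2 while the other 5 mouse arrays lie between 2.06 and 24.5.

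Between the mouse morula and blastocyst, 1066 of 16860 genes changed, of which 650 were higher and 416 lower in the blastocyst. The largest rise was that of ENSMUSG00000074207_at, from 4.79 ± 0.02 in the morula to 13.1 ± 0.05 in the blastocyst, a 314-fold difference (log2 fold change 8.29, SE 0.24, adjusted p = 0.000586). ENSMUSG00000046361_at rose from 4.48 ± 2.41 to 11.3 ± 0.06 (adjusted p = 0.0223), with morula pools that themselves stood at 2.78 and 6.18. The largest falls were those of ENSMUSG00000056054_at, from 9.56 ± 0.24 to 3.53 ± 0.11 (adjusted p = 0.00492), and ENSMUSG00000000204_at, from 8.82 ± 0.13 to 2.94 ± 0.25 (adjusted p = 0.00339). In the isolated ICM these 4 genes stood close to their blastocyst means, at 13.0 ± 0.13, 11.3 ± 0.46, 3.74 ± 0.90 and 3.06 ± 0.53. Of the called genes 332 were at least 4-fold higher and 195 at least 4-fold lower, and 107 and 60 passed 8-fold. Called genes are large changes by selection, and over all 16860 genes the SD of the log2 fold change was 0.94.

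Some of the called mouse genes crossed from the lower to the upper part of the table or back. In the blastocyst 99 of the 650 higher genes had risen from below the 25th percentile of all mouse values (4.79) to above the median (6.38), and 72 of the 416 lower genes had gone the opposite way. The shares were 15.2% and 17.3% (Fisher's exact test, two-sided p = 0.393, which treats genes as independent). Taken over all genes, the difference in one pair of pools predicted the difference in the other with a correlation of 0.669 for pools paired by number and 0.667 for pools paired crosswise. At least 2-fold rises recurred in both pairs at 1212 genes and falls at 945, against 267 and 274 for independent lists, and 92 genes were at least 2-fold changed in opposite directions.

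Over all mouse genes the median log2 fold change of the blastocyst against the morula was -0.15 as deposited. It was -0.05 after quantile normalisation and -0.19 with a common median, against a smallest called change of 1.11. With a common median 581 genes were called higher and 453 lower, and after quantile normalisation 628 and 417. The count depended on the arrays that set the spread: it was 1863 without either ICM pool, 422 without morula pool 1, 623 without morula pool 2, and 1 without either blastocyst pool, that gene being ENSMUSG00000074207_at.

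**Figure D2:**
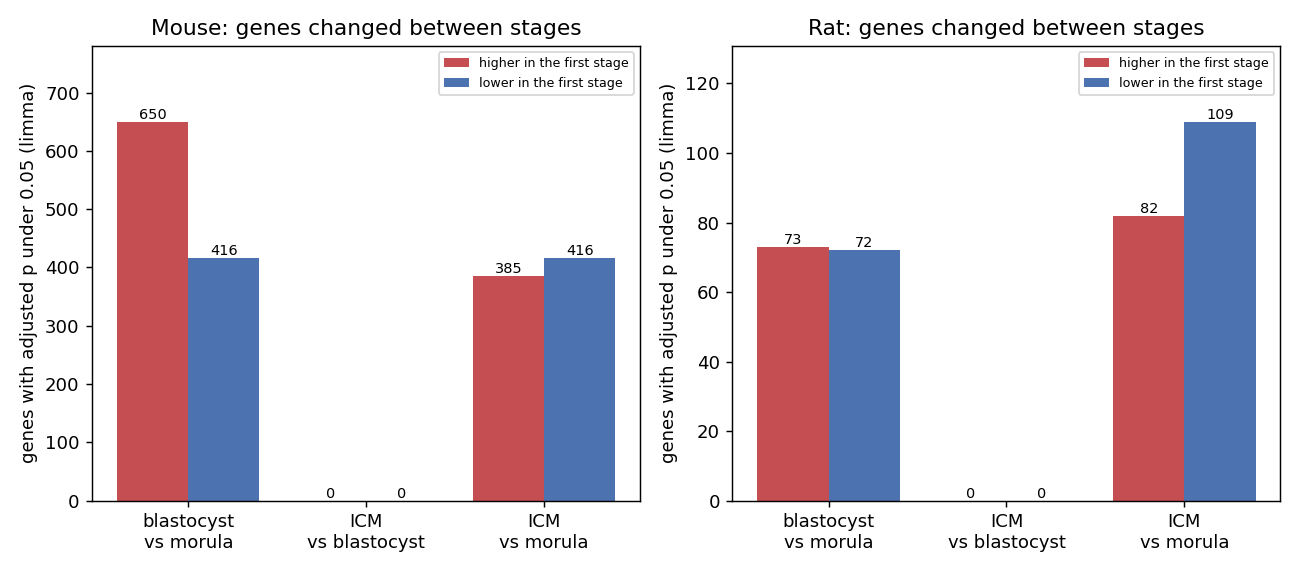
Number of genes past an adjusted p of 0.05 (limma) for each pair of stages, in the mouse (left, 16860 genes) and the rat (right, 11462 genes), with separate vertical scales. Red bars count genes higher and blue bars genes lower in the first-named stage: the blastocyst against the morula gave 650 and 416 genes in the mouse and 73 and 72 in the rat, and the ICM against the blastocyst gave none in either species.

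Between the rat morula and blastocyst, 145 of 11462 genes changed, 73 higher and 72 lower in the blastocyst. ENSRNOG00000020270_at rose most, from 2.60 ± 0.20 to 8.95 ± 0.20 (81.4-fold, log2 fold change 6.35, SE 0.24, adjusted p = 0.00514). ENSRNOG00000008855_at rose from 4.41 ± 0.25 to 10.1 ± 0.59 (adjusted p = 0.00872) and stood higher still in the ICM, at 11.5 ± 0.02. The largest falls were those of ENSRNOG00000007886_at, from 10.1 ± 0.50 to 3.21 ± 0.10 (adjusted p = 0.00518), and ENSRNOG00000030539_at, from 10.6 ± 0.50 to 3.84 ± 1.16 (adjusted p = 0.0225). In the limma fit on the 4 arrays of these 2 stages, ENSRNOG00000008855_at (adjusted p = 0.0547) and ENSRNOG00000030539_at (adjusted p = 0.0765) did not pass. Of the called genes 50 were at least 4-fold higher and 60 at least 4-fold lower.

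Some of the called rat genes also crossed between the lower and the upper part of the table. Of the 72 lower genes, 22 (30.6%) went from above the table's median (5.73) to below its 25th percentile (3.79), against 10 of the 73 higher genes (13.7%) in the opposite direction (Fisher's exact test, two-sided p = 0.0168, which treats genes as independent and so overstates the evidence). Called falls were also larger than called rises (median log2 fold change -2.95 against 2.35), and larger changes cross these limits more readily. Over all genes the differences in separate pairs of pools correlated at 0.347 by number and 0.395 crosswise. Rises of at least 2-fold recurred at 409 genes and falls at 332, against 120 and 110 for independent lists, and 163 genes went opposite ways. The count of calls rested on single arrays: it was 395 without morula pool 1, 72 without morula pool 2 and 7 without either ICM pool. It was 0 without blastocyst pool 1 or 2, with 1465 and 1198 genes at an unadjusted p under 0.05.

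**Figure D3:**
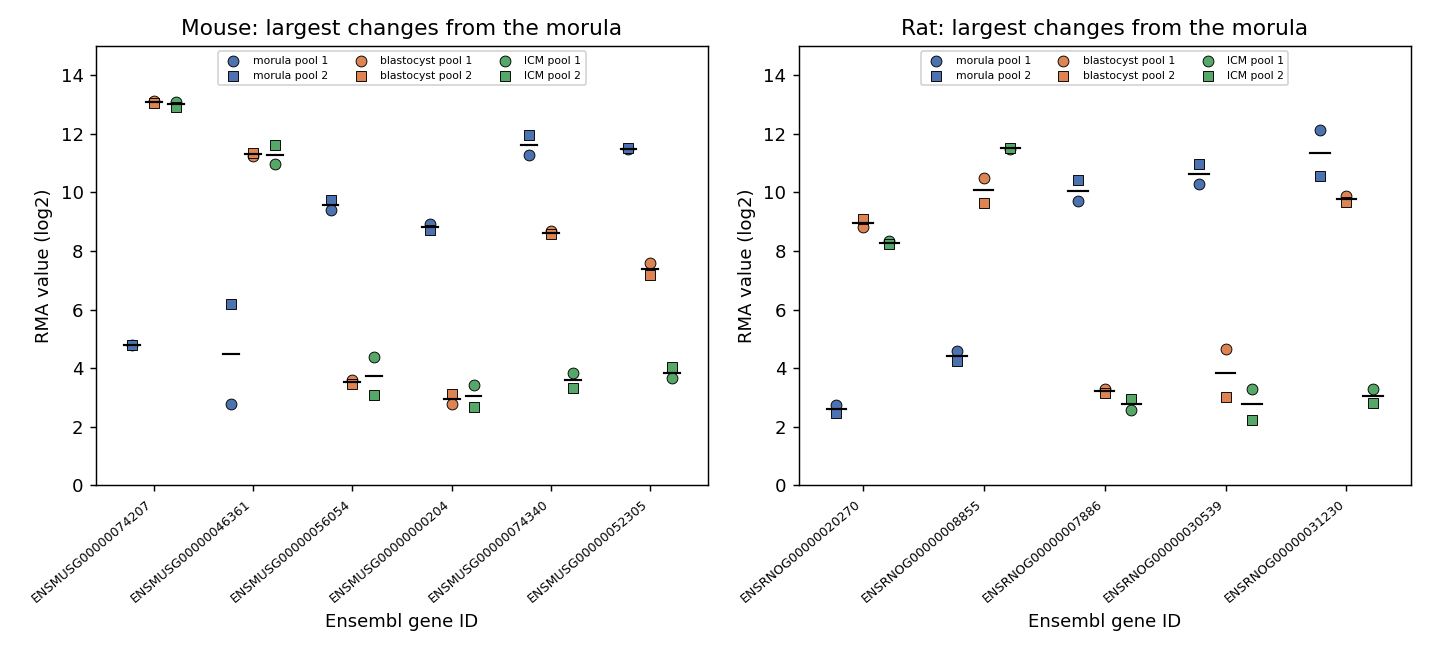
RMA log2 value of each pool for the genes with the largest called rises and falls from the morula, in the mouse (left) and the rat (right), with points for single pools (circle for pool 1, square for pool 2) coloured by stage and short bars for the means of 2 pools. ENSMUSG00000074207_at lies near 4.79 in both morula pools and between 12.9 and 13.1 in the other 4 pools, and ENSRNOG00000031230_at lies at 2.81 and 3.29 in the rat ICM pools and above 9 in the other 4.

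The isolated ICM was set against the whole blastocyst to ask which transcripts mark the inner cells and which mark the trophectoderm that immunosurgery removes. Only the ICM pools had been treated with antiserum and serum complement. In any comparison of the ICM, effects of that treatment cannot be told apart from the loss of the outer cells. Maternal tissue carried along with the embryos could not be judged either, since its markers could not be read. No gene passed the threshold in either species with limma. Unadjusted p-values under 0.05 were found for 1035 mouse genes, where 843 would be so by chance, and for 702 rat genes, where chance gives 573. The largest mouse falls in the ICM with pools that did not overlap were those of ENSMUSG00000074340_at, from 8.63 ± 0.06 to 3.58 ± 0.37 (33.0-fold, adjusted p = 0.0979), and of ENSMUSG00000052305_at, from 7.39 ± 0.31 to 3.85 ± 0.26 (adjusted p = 0.134). Higher in the mouse ICM were ENSMUSG00000038418_at, at 10.3 ± 0.67 against 6.22 ± 0.05 (adjusted p = 0.348), and ENSMUSG00000021250_at, at 8.08 ± 1.09 against 4.54 ± 0.35 (adjusted p = 0.675). In the rat, ENSRNOG00000031230_at stood at 9.77 ± 0.13 in the blastocyst and 3.05 ± 0.33 in the ICM (105-fold, adjusted p = 0.106). ENSRNOG00000033465_at stood at 10.6 ± 0.00 and 5.28 ± 0.34 (adjusted p = 0.106). Higher in the rat ICM were ENSRNOG00000012772_at, at 7.93 ± 0.34 against 3.44 ± 0.75 (adjusted p = 0.144), and ENSRNOG00000009481_at, at 8.73 ± 0.30 against 4.64 ± 0.17 (adjusted p = 0.529). These 8 genes were chosen after their values were seen, as the largest differences whose pools did not overlap.

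Differences between the ICM and the blastocyst nevertheless recurred between pools. Separate pairs of pools correlated over genes at 0.239 by number and 0.240 crosswise in the mouse, and at 0.202 and 0.217 in the rat. In the mouse 68 genes were at least 2-fold higher and 112 at least 2-fold lower in the ICM in both pairs, against 33.7 and 37.1 for independent lists, and 54 genes went at least 2-fold in opposite directions. In the rat the counts were 105 and 159, against 29.6 and 39.1, with 83 in opposite directions. Genes that vary widely in every pool can pass 2-fold in both pairs in any direction. Independent lists leave this out, here and for the blastocyst against the morula, so these baselines can be too low. The SD of repeated differences was 0.31 in the mouse and 0.31 in the rat on the log2 scale. It was 0.25 and 0.32 after quantile normalisation and 0.30 and 0.36 without dim genes, so the equality of the species depended on the processing. Without mouse ICM pool 1 the mouse count remained 0, with 737 genes at an unadjusted p under 0.05, and without ICM pool 2 it was 0 with 4674 such genes. The rat count was 2 without either morula pool, from ENSRNOG00000031230_at and ENSRNOG00000033465_at. Under a mean-dependent prior, 1 mouse gene (ENSMUSG00000074340_at, adjusted p = 0.02) and 3 rat genes passed, namely ENSRNOG00000031230_at (adjusted p = 0.0116), ENSRNOG00000033465_at (adjusted p = 0.00709) and ENSRNOG00000014117_at, which was higher in the ICM (log2 fold change 3.59, adjusted p = 0.00709).

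**Figure D4:**
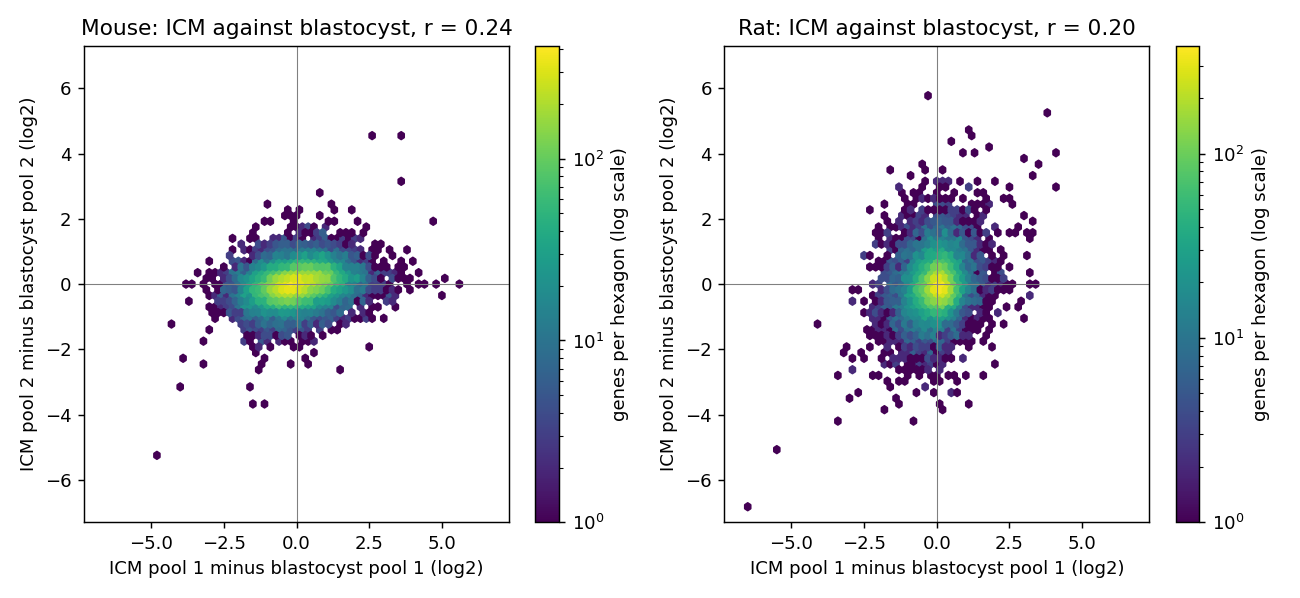
Density of genes by the ICM minus blastocyst difference (log2) in pool pair 1 (horizontal) and pool pair 2 (vertical), in the mouse (left) and the rat (right), with colour for the number of genes per hexagon on a log scale. The mouse cloud is wide along the axis of ICM pool 1, where 3908 genes were at least 2-fold changed against 616 in pair 2, and the correlations are 0.239 and 0.202.

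Against the morula, the mouse ICM differed at 801 genes, 385 higher and 416 lower, and the rat ICM at 191 genes, 82 higher and 109 lower. The largest mouse falls were those of ENSMUSG00000074340_at, from 11.6 ± 0.50 in the morula to 3.58 ± 0.37 (262-fold, log2 fold change -8.03, SE 0.34, adjusted p = 0.00204), and ENSMUSG00000052305_at, from 11.5 ± 0.03 to 3.85 ± 0.26 (adjusted p = 0.00137). Both were at intermediate values in the whole blastocyst, as given above. The largest mouse rises were again those of ENSMUSG00000074207_at, to 13.0 ± 0.13 (adjusted p = 0.000624), and ENSMUSG00000046361_at, to 11.3 ± 0.46 (adjusted p = 0.0257). The latter did not pass in the limma fit on the 4 arrays of these 2 stages (adjusted p = 0.064). In the rat ICM, ENSRNOG00000008855_at (136-fold, adjusted p = 0.00382) and ENSRNOG00000020270_at (51.2-fold, adjusted p = 0.00382) rose most. ENSRNOG00000031230_at fell from 11.3 ± 1.13 to 3.05 ± 0.33 (314-fold, adjusted p = 0.0101) and ENSRNOG00000030539_at from 10.6 ± 0.50 to 2.76 ± 0.76 (adjusted p = 0.0129). In the limma fit on the 4 arrays of these 2 stages, ENSRNOG00000031230_at did not pass (adjusted p = 0.0683). The mouse count was 399 without ICM pool 1, 1154 without ICM pool 2, 310 and 460 without morula pools 1 and 2, and 98 without either blastocyst pool. The rat count was 0 without ICM pool 1 or 2, with 1220 and 1203 genes at an unadjusted p under 0.05. It was 441 and 120 without morula pools 1 and 2, and 19 without either blastocyst pool.

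Many of the genes that separated the blastocyst from the morula also separated the ICM from it. In the mouse 344 genes were called higher and 287 lower than the morula in both the blastocyst and the ICM, and none was called in opposite directions. In the rat the counts were 44 and 61, again with none opposite. Independent lists would share 14.8 and 10.3 genes in the mouse and 0.52 and 0.68 in the rat. Both comparisons used the same morula pools, which raises the overlap. A single simulated set of unchanged groups shared 0 called genes in each species. Such groups yield almost no calls, so this does not measure how far the shared pools raised the counts. The fold changes correlated at 0.825 in the mouse and 0.797 in the rat. Simulated unchanged groups gave 0.50 (mean of 50 simulations), a value fixed by giving every stage the same spread per gene. The covariance was 0.678 in the mouse against a simulated 0.116, and 0.533 in the rat against 0.126. Measured spreads were unequal: the root-mean-square SD between pools was 0.549, 0.224 and 0.585 in mouse morulae, blastocysts and ICMs. Rat values were 0.622, 0.444 and 0.404. The simulated values therefore understate what the shared morula pools add, and the excess over them is not sized here. With the morula pools kept apart, mouse ICM pool 1 held 58.3% and ICM pool 2 held 91.6% of the morula-to-blastocyst change (74.9% ± 23.5, SD, n = 2). The shares were 74.1% and 94.8% after quantile normalisation and 66.4% and 92.8% without dim genes. Rat ICM pools held 99.9% and 100.8% (100.4% ± 0.67, SD, n = 2). The rat shares were 98.0% and 97.6% after quantile normalisation and 98.7% and 98.8% without dim genes. The SDs of these shares cover the ICM pools alone, since both shares of a species used the same morula and blastocyst pools and divisor. The SD of repeated differences behind the rat divisor was 0.57 by number and 0.60 crosswise.

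The 2 species can be set side by side only as summaries, because their tables were made separately and their genes were not matched here. Of the genes tested, 6.32% changed between morula and blastocyst in the mouse and 1.27% in the rat. Both shares moved with the arrays that set the spread, as the counts above show. The SD of repeated differences for that step was 0.84 in the mouse and 0.58 in the rat, whereas for the ICM against the morula it was 0.67 and 0.66. The median SD between pools was 0.27 in the morulae of both species, 0.11 in mouse and 0.25 in rat blastocysts, and 0.34 in mouse and 0.17 in rat ICMs. No test of a difference between the species was made.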

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

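Array quality weights, and the alternatives for the measure over separate pool pairs, were chosen after the result was seen. With 2 arrays per stage they are equal within a stage and act as a weight per stage. Quantile normalisation, a common median and removal of the dimmest 30% of genes left all 6 counts within 1.5 times their value. The added 2-fold minimum could change no count, since the smallest called log2 change was 1.11 and a count of 0 cannot fall. With a mean-dependent prior the counts for the blastocyst against the morula rose to 1627 in the mouse and 236 in the rat, those for the ICM against the morula to 1396 and 359, and those for the ICM against the blastocyst to 1 and 3. Fits on the 4 arrays of the 2 stages alone gave 1863 and 7 for the blastocyst against the morula, 98 and 19 for the ICM against the morula, and 0 and 2 for the ICM against the blastocyst (1245 mouse genes at an unadjusted p under 0.05). Array weights gave 2563 and 51, 230 and 201, and 1 and 3 in the same order. The 1 mouse gene was ENSMUSG00000074340_at in both settings that called it, the 2 rat genes were ENSRNOG00000031230_at and ENSRNOG00000033465_at, and the 3 rat genes were these and ENSRNOG00000014117_at in both settings. Over the 6 fits that each left out 1 array, the count ran from 1 to 1863 for the mouse blastocyst against the morula, from 98 to 1154 for the mouse ICM against the morula, and stayed at 0 for the mouse ICM against the blastocyst. In the rat the ranges were 0 to 395, 0 to 441 and 0 to 2. In such a fit the lone pool of a stage is assumed to vary like the other stages, and the spread comes only from the stages with both pools. Leaving out an ICM pool therefore gives the same count for blastocyst against morula as the fit on 4 arrays, and leaving out a mouse blastocyst pool removes the pair with the smallest spread. Of 223 refits of the 16 values behind the genes named as called, none turned its sign and 37 lost the threshold, 33 of them when an array was left out and 4 in fits on 4 arrays. Those 16 values had been picked as the largest changes. The mean-dependent prior, the 2-fold minimum, the fits on 4 arrays and the replicate block leave the fold change itself unaltered, so no sign could turn there. The same holds for removal of dim genes, for array weights and for leaving out a pool of the stage not compared. The replicate numbers did not pair the samples: deviations of same-numbered pools correlated between -0.06 and 0.07 over the 3 pairs of stages in each species. With the replicate block the counts were 771 and 30 for the blastocyst against the morula, 512 and 76 for the ICM against the morula, and 0 and 0 for the ICM against the blastocyst (1060 and 651 genes at an unadjusted p under 0.05). The correlation between separate pool pairs for the mouse ICM against the blastocyst was 0.18 after quantile normalisation and 0.25 without dim genes. Leaving out an array was not possible for this measure, which needs 2 pools per stage. The alternative of averaging probe sets did not apply, and the planned tests of gene lists and of matched mouse and rat genes were not run because no ID could be named or matched. Signal over background could not be judged without scanner values, and changes of 1 on the log2 scale were almost never recovered in simulated data.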

Other observations

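The tests of a compressed value range and of compression throughout the rat table, and the counts over both steps together, were chosen only after the result was seen. The 2 steps from morula to blastocyst and from blastocyst to ICM were also read together, gene by gene, keeping genes whose pools did not overlap and whose means differed by at least 2-fold at each step. In the mouse 191 genes were highest in the whole blastocyst, above both the morula and the ICM, and 39 fell at both steps, among them ENSMUSG00000074340_at (11.6, 8.63 and 3.58 in morula, blastocyst and ICM), while 4 rose at both. In the rat 134 genes were highest in the whole blastocyst, 23 rose at both steps and 23 fell at both. Simulations set the ICM equal to the blastocyst and used a single spread per gene for all stages. They gave 114 genes highest in the blastocyst in the mouse (at most 128 in 20 simulations) and 79.9 in the rat (at most 93). Genes falling at both steps numbered 27.1 in the mouse simulations (at most 35) and 24.1 in those of the rat (at most 38), so the rat count was at the simulated level. Genes rising at both steps numbered 22.5 (at most 31), above the mouse count, and 13.3 in the rat (at most 21). Genes lowest in the blastocyst were not in excess, with 111 in the mouse against 132 simulated and 55 in the rat against 95.4. The measured spread differed between stages, with a median SD between pools of 0.11 in mouse blastocysts and 0.34 in mouse ICMs. Measured and simulated counts can differ through that alone, so no excess is read from them. These counts came from the same arrays as the comparisons and were not tested further.

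Mouse ICM pool 1 stood apart from every other blastocyst-stage array of the mouse. A narrower value range was present, with an SD over genes of 2.13 against 2.35 in ICM pool 2. Spearman correlation with the blastocyst mean, which a monotone compression of the values leaves alone, was still 0.0603 lower for pool 1 than for pool 2. Compression of the values alone therefore cannot be the whole cause. A compressed signal under unchanged noise would also lower this correlation, so the test does not exclude a narrower signal range. Noise in pool 1 stays open, since the correlation of 0.240 between the pools' differences from separate blastocyst pools shows only that some difference is shared, which the bound set beforehand did not allow for, and the shared covariance was 0.0954 against a variance of 0.745 for pool 1 and 0.181 for pool 2. Whether pool 2 kept more trophectoderm than pool 1 is open too: its differences followed those of pool 1 with a slope of 0.124, which such a remainder allows, but no trophectoderm marker could be read and no biological difference between the pools is named by the labels.

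Fewer rat than mouse genes were called between morula and blastocyst. In the fit behind the calls the median SE was 0.338 in the mouse and 0.318 in the rat. Between blastocyst pools the median SD was nevertheless larger in the rat (0.25 against 0.11). A larger spread between rat pools is argued against as the whole cause, since the SD of repeated differences, which the spread between separate pools does not inflate, was itself 0.694 times the mouse value (0.675 and 0.711 for the 2 ways of pairing the pools). If the mouse blastocyst arrays were repeats of one RNA, the mouse value would be raised and the ratio lowered. That ratio is consistent with smaller changes over the sampled interval in the rat, in which morula and blastocyst were collected at days 4 and 4.5, while the interval in the mouse is not given by the labels. Compression of all fold changes in the rat table stays open: for the ICM against the morula the ratio was 0.986, which points the other way, but it rests on mouse ICM pool 1. The 2 tables hold different sets of genes, and no species difference was tested gene by gene.

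Rat morula pool 1 lay nearer than pool 2 to the blastocyst pools, with correlations of 0.940 and 0.933 against 0.925 and 0.913. These are values for single pools, and no order of the pools in developmental time is read from them.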
